A study of Mus musculus with 6 samples.

How the data were processed

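Cells of joint capsule and quadriceps were taken 14 days after ACL transection, per the labels' protocols from tissue pooled over 8 mice, and cells of the injured limb were sorted on SPiDER-βGal fluorescence before droplet capture. The 6 libraries, 1 per group, were the uninjured, injured SPiDER-negative and injured SPiDER-positive fractions of each tissue. The deposited matrices hold UMI counts per gene and barcode, which the authors made with Cell Ranger 6.0 on the builds mm10 and mm39, per the submitters' processing notes. The aligner settings and the annotation release of each library are not given in the sources used here. The joint uninjured library came with another feature table than the other 5, so genes were matched by Ensembl ID, which left 30406 genes shared by all 6.

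Barcodes with at least 300 genes and under 15% mitochondrial UMIs were kept, and doublets called by Scrublet within each library were removed. In the order of joint uninjured, negative and positive and quadriceps uninjured, negative and positive, this kept 10045, 12066, 3757, 10448, 9812 and 14719 cells of 64367 barcodes in all, with 121970882, 82684364, 46831137, 72012710, 79567544 and 138132749 UMIs. Median UMIs per kept cell were 8664, 3532, 10843, 6312, 6882 and 5825, median genes 1991, 1081, 2873, 2166, 2216 and 1873, and median mitochondrial shares 1.09%, 1.31%, 3.06%, 2.55%, 2.02% and 5.36%. Scrublet called 0, 0, 34, 221, 270 and 1 doublets, against expected rates of 8.04%, 9.65%, 3.03%, 8.54%, 8.07% and 11.8%. It did not work for joint uninjured, joint negative and quadriceps positive, where it called under 0.5% of cells.

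The 3 libraries of a tissue were clustered together with scanpy 1.11.5 on 2000 variable genes chosen across libraries, 30 principal components and 15 neighbors, with Leiden clustering (igraph 0.11.9) at resolution 1.0 and seed 1. Libraries were not integrated. A cluster was named for the class with the largest share of fixed markers raised. It stayed unnamed with under 3 raised, leading genes of another class, or low UMIs and no marker in its top 10 genes. UMIs were summed per library and class and given as CPM, scaled to a common total, with log2 ratios of CPM plus a pseudocount of 5. Classes other than macrophage-like cells needed 50 cells and 100000 UMIs in both libraries. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, matplotlib 3.10.9, R 4.3.3 and edgeR 4.0.16, for the trimmed mean of M-values factors of an alternative, were used.

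The groups, comparisons, 21 gene lists, marker genes, naming rule and 27 pairs of a result and an alternative were chosen before the data were examined, and 8 pairs were added afterward. With 1 pooled library per group no test was made. Sums carry exact Poisson intervals and shares exact Clopper-Pearson intervals, at 95% and for counting error only, and mice, sorting and capture add variation that these data do not measure. Named genes were the 10 highest and 10 lowest log2 ratios in macrophage-like cells, and 5 and 5 in up to 3 further classes per tissue, among genes with at least 50 CPM and 100 UMIs in the higher library, intervals apart, and at least 0.5 times the CPM of all other cells of that library. Mitochondrial, ribosomal protein, hemoglobin, immunoglobulin and unnamed predicted genes were not named, and 13 genes were always given in macrophage-like cells. List members needed 10 CPM in either library, those counted as 1.5-fold higher or lower also had intervals apart, and each median was placed among 10000 random lists matched on expression in 20 bins. For shares of cells with a UMI, each cell was thinned to 2000 UMIs. Beside a share or CPM of 0, the limit given is that of 3 counts over the cells or UMIs, in place of the exact interval.

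The steps from summed counts to gene differences and lists were tested on simulated data at the depth of each comparison, with 100 genes at each fold size. Genes built 2-fold apart were recovered in 100% of cases in the quadriceps sort, 78% in the joint sort, 100% in the quadriceps injury and 72% in the joint injury contrast. At 4-fold they were 100%, 98%, 100% and 96% in that order. Unchanged genes were called different in 0%, 1.54%, 0% and 0.664% of cases. Of 200 unchanged lists, 5%, 4.50%, 2.50% and 4% fell outside the central 95% of random lists. The simulation covers counting error and neither clustering nor variation among cells or mice. A check for mixed-up samples on Xist and Y-linked RNA could not decide, because all 6 libraries held both.

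Alternatives changed the gene minimum, mitochondrial limit, doublet removal, clustering resolution, joint clustering of both tissues, class definition, proliferating cells, normalization, pseudocount, gene matching, expression minimum, thinning and subtraction of free RNA. The subtraction from hemoglobin was not run for the quadriceps sort contrast, because the hemoglobin share of its positive macrophage-like cells was 148% of that of the whole library.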

Results

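Single-cell RNA counts were collected from 6 mouse libraries, 3 of joint capsule and 3 of quadriceps, 14 days after transection of the anterior cruciate ligament (ACL). Each library held tissue pooled from 8 mice. Within each tissue 1 library came from the uninjured limb and 2 came from the injured limb, sorted by the dye SPiDER-βGal into cells with and without senescence-associated β-galactosidase activity. That lysosomal activity is widely used as a mark of cellular senescence and is also high in macrophages, which are rich in lysosomes. The titles of the uninjured libraries give no gate while their library names contain neg, so whether these cells were sorted on the dye is not known. Joint totals were 123163399 UMIs (unique molecular identifiers) in the uninjured, 83772366 in the injured SPiDER-negative and 48230754 in the injured SPiDER-positive library, in 10349, 12456 and 4176 barcodes. Quadriceps totals were 74602377, 83532995 and 140778221 UMIs in 11158, 10491 and 15737 barcodes, in the same order. Median UMIs per barcode were 8481, 3344 and 10028 in joint and 6062, 6601 and 4985 in quadriceps. With 1 library per group there was no replicate and no test, and each interval given covers counting error only.

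The first question was which cells carried the dye. Macrophage-like cells made up 47.1% (1771 of 3757 cells, 95% interval 45.5 to 48.7%) of the joint SPiDER-positive library, 0.298% (36 of 12066, 0.209 to 0.413%) of the SPiDER-negative library and 0.946% (95 of 10045, 0.766 to 1.15%) of the uninjured library. In quadriceps they made up 40.2% (5924 of 14719, 39.5 to 41.0%) of the SPiDER-positive, 6.35% (623 of 9812, 5.87 to 6.85%) of the SPiDER-negative and 2.99% (312 of 10448, 2.67 to 3.33%) of the uninjured library. Over the alternatives the shares ran from 0.264 to 11.4% in negative and 43.4 to 52.1% in positive joint. In quadriceps these were 4.35 to 21.7% and 32.1 to 90.8%. Synovial lining fibroblast-like cells, led by Prg4 and Htra4, held 0.767%, 0.381% and 28.4% of the uninjured, negative and positive joint libraries. Joint neutrophil-like cells held 31.4%, 29.6% and 2.98%, monocyte-like cells 14.9%, 11.1% and 1.20%, marrow granulocyte precursor-like cells 11.0%, 30.3% and 0.985%, fibroblast-like cells 7.18%, 4.29% and 5.35% and chondrocyte-like cells 1.17%, 0.613% and 2.05% in that order. Of the 3656 precursor-like cells of the negative joint library, 72.7% lay in a cluster of low UMI count that came almost wholly from that library. In quadriceps, fibroblast-like cells held 57.2%, 39.2% and 4.97% of the uninjured, negative and positive libraries, endothelial-like cells 8.90%, 4.63% and 1.13%, monocyte-like cells 2.30%, 11.8% and 1.34%, dendritic cell-like cells 1.79%, 6.80% and 0.204% and satellite or myogenic-like cells 5.64%, 2.36% and 0.741%. The sort set these shares, so shares of the positive and negative libraries are not shares of the injured tissue, nor those of the uninjured libraries shares of uninjured tissue if these were sorted too.

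**Figure D1:**
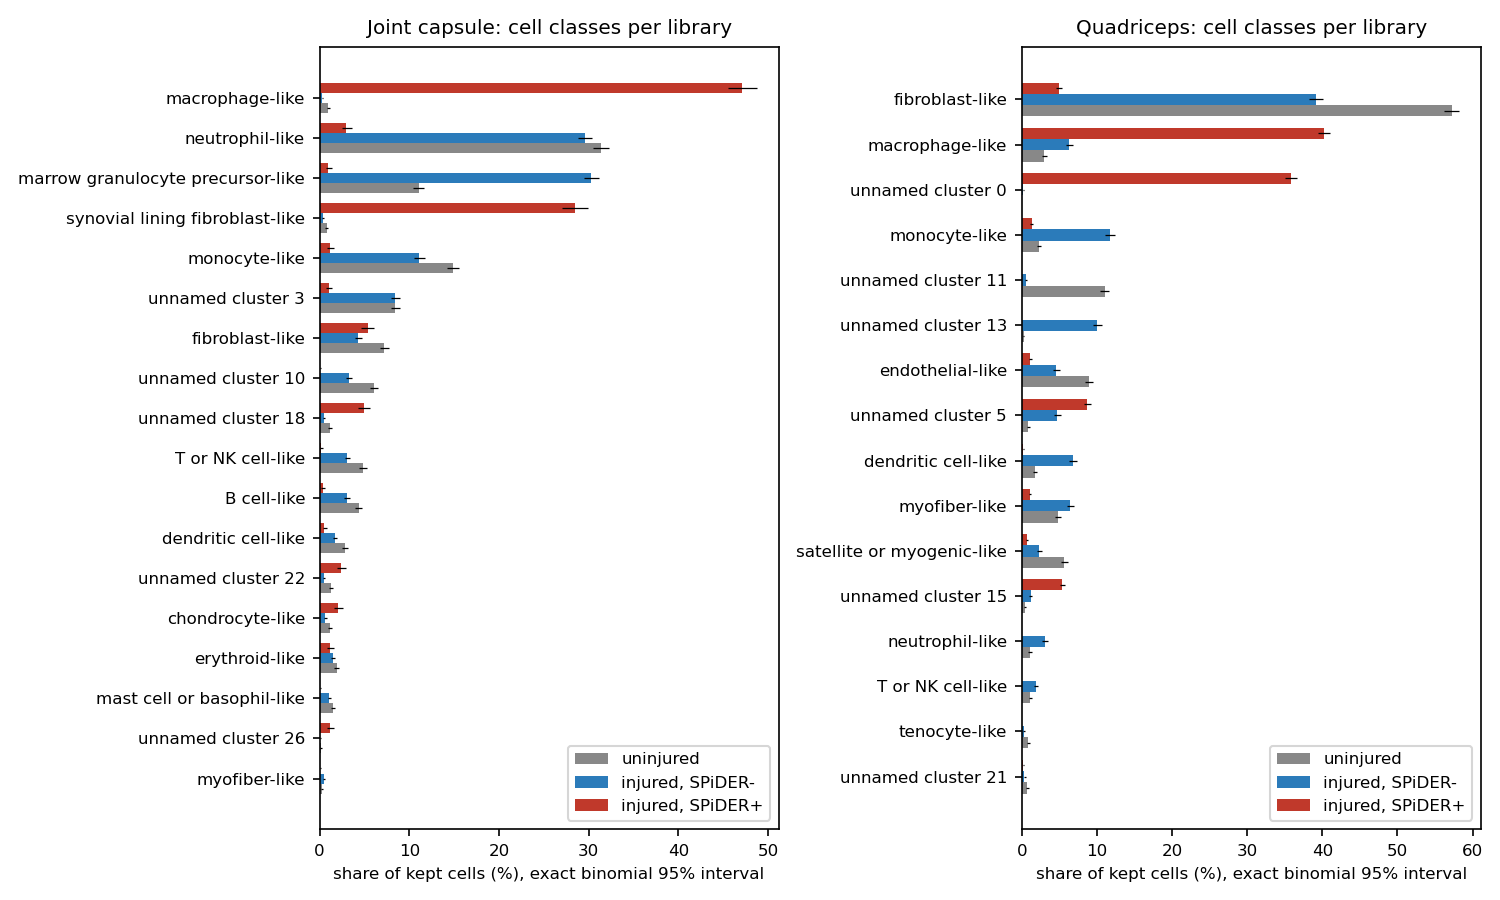
Share of kept cells (percent, x axis) of each cell class in the 3 joint and the 3 quadriceps libraries, with exact binomial 95% intervals as error bars. Macrophage-like cells held 47.1% of the SPiDER-positive joint library and 40.2% of the SPiDER-positive quadriceps library.

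Several clusters received no class name. In the positive quadriceps library, cluster 0, with a median of 901 UMIs per cell, held 35.9% of cells against 0.224% in the negative and 0.0191% in the uninjured library, and was led by Ccl8, Wfdc17 and Ccl12. Cluster 5, led by Syngr1, Gpnmb, Spp1 and Fabp5, held 0.861%, 4.73% and 8.70% of the uninjured, negative and positive libraries, and cluster 15, led by Lyz1, Mmp12 and Retnla, held 0.440%, 1.19% and 5.41%. Cluster 11, led by hemoglobin genes and Ccl11, held 11.0%, 0.581% and 0.0136%, cluster 13, led by Cthrc1, Plac8 and Postn, 0.239%, 10.1% and 0.0340%, and the pericyte-gene cluster 21 0.737%, 0.367% and 0.190%. In joint, cluster 18, led by Cxcl3, Acp5 and Mmp19 with Ctsk and Atp6v0d2, held 1.15%, 0.497% and 4.92%, and cluster 22, with endothelial and mural genes, 1.23%, 0.439% and 2.42%. The granule-gene clusters 3 and 10, led by Ltf and Ngp, held 8.45%, 8.41% and 1.01% and 6.06%, 3.23% and 0.0266%, and the Cxcl12 and Lepr cluster 26 0.159%, 0.0580% and 1.20%. With unnamed clusters of macrophage markers added, quadriceps macrophage-like shares were 4.31%, 12.5% and 90.2% (uninjured, negative, positive). Cluster 0, which free RNA may account for, is part of the 90.2%.

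The quadriceps sort contrast asked how macrophage-like cells with the dye differed from those without it. SPiDER-positive cells had higher resident-type and lysosomal transcripts, and lower MHC class II and monocyte transcripts, than SPiDER-negative cells of the same injured muscles. Among genes that met the naming rule, which asked for at least 50 CPM (UMI counts scaled to a common total) and 100 UMIs in the higher library and intervals apart, the 10 with the largest positive ratios were Ccl8 at 928 against 75.8, Saa3 at 145 against 11.1, Cd209f at 179 against 17.3, Cd209g at 62.0 against 4.88 and C4b at 125 against 14.2 CPM. Next were Fcna at 132 against 19.98, Ednrb at 319 against 56.4, Retnla at 734 against 151, Mt2 at 416 against 87.3 and Cd209d at 69.0 against 11.5 CPM. The 10 with the largest negative ratios were Il1r2 at 2.16 against 87.7, Ccr7 at 0.454 against 54.2, Il1b at 92.5 against 852, Cytip at 37.1 against 357 and Napsa at 15.1 against 158 CPM. These were followed by Ccl17 at 2.84 against 54.3, Plbd1 at 30.2 against 222, Itgb7 at 8.42 against 68.4, Cd209a at 21.6 against 123 and Hist1h1b at 179 against 749.6 CPM. Of the resident-type list's 19 measured members, 19 were at least 1.5-fold higher and 0 at least 1.5-fold lower in the positive cells, with Gas6 at 417 against 94.3 CPM and Cd163 at 153 against 44.5 CPM. Its median was 1.63 and ran from 0.53 to 2.22 over the alternatives. The lysosome list had a median log2 ratio of 0.52, and of its 34 measured members, 16 were at least 1.5-fold higher and 0 at least 1.5-fold lower, with Ctsd at 1809 against 775, Ctsb at 4087 against 2062, Ctsl at 1517 against 763 and Tpp1 at 142 against 69.2 CPM. The MHC class II list had a median of -1.57, with H2-Ab1 at 820.0 against 2919 and H2-Eb1 at 760.3 against 2574 CPM, but a median of 0.014 with finer clusters at Leiden resolution 2.0 and of -0.23 without proliferating cells. H2-Ab1, H2-Eb1, Ccr7, Cytip, Napsa, Ccl17 and Cd209a are also among the 10 leading genes of the dendritic cell-like cluster 17, so dendritic-like cells counted as macrophage-like were not separable from a macrophage state. The recruited monocyte list had one of -0.69, with Ms4a4c at 52.0 against 156 and Ly6c2 at 9.41 against 34.0 CPM, and ran from -1.65 to -0.37. Median log2 ratios were 0.78 for complement, 0.52 for lipid-associated macrophage, 0.45 for iron handling and oxidative stress and 0.43 for NF-kB and inflammatory cytokines. Smaller ones were 0.41 for collagen and matrix, 0.33 for muscle atrophy and denervation, 0.31 for secreted factors acting on muscle and 0.23 for matrix proteases and inhibitors. The collagen and matrix median was -0.051 with monocyte-like cells counted in, -0.20 without proliferating cells, -0.28 by the mean of CPM per cell and -0.18 with the cluster mix held equal, and the NF-kB median was -0.0061 without proliferating cells. The remaining medians were 0.12 for interferon response, 0.056 for immediate early and heat shock and -0.064 for oxidative phosphorylation. Lowest were -0.34 for glycolysis and hypoxia and -0.56 for proliferation. Over the alternatives the median ran from -0.20 to 0.69 for secreted factors acting on muscle, -0.22 to 0.49 for matrix proteases, -0.27 to 0.75 for interferon response and -0.67 to 0.60 for proliferation. The immediate early and oxidative phosphorylation medians also took both signs.

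The clusters behind this contrast differed. Cluster 3, led by Cd209f, Cd163 and Lyve1, held 40.0% of the positive and 13.002% of the negative macrophage-like cells, and the proliferating cluster 16, led by histone genes and Top2a, held 12.4% and 27.4%. Cluster 1, led by Il10 and Ccl12, held 46.7% and 49.0%, and the low-UMI cluster 22 0.827% and 10.6%. Cluster 3 held 90.6% of the positive library's Cd209f UMIs, and cluster 16 held 87.6% of the negative library's Il1b UMIs, 98.4% of its Ccr7 UMIs, 92.9% of its Cytip UMIs and 91.1% of its Napsa UMIs. The 12 negative cells with the most UMIs of each gene held 81.1% of the Ccr7, 85.6% of the Ccl17, 71.5% of the Cd209a, 53.8% of the Il1b and 47.7% of the Il1r2 UMIs, and without them these genes were at 10.6, 8.27, 36.1, 409 and 47.7 CPM in the negative cells. With the cluster mix held equal, the lysosome median was 0.22 and the proliferation median 0.16, the opposite sign. Cd209a was higher rather than lower, at a log2 ratio of 1.98, once proliferating cells were left out, and so was Hist1h1b, at 0.46.

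Genes tied to senescence split in the quadriceps macrophage-like cells. Cdkn1a (p21, ENSMUSG00000023067) was at 717 CPM (95% interval 711 to 723) against 653 CPM (634 to 673), a 1.10-fold difference with a counting interval of 1.06 to 1.13. This direction changed sign without proliferating cells, at -0.12. Cdkn2a (p16, ENSMUSG00000044303) was at 1.89 CPM (95% interval 1.58 to 2.24) against 1.78 CPM (0.917 to 3.10), from 133 and 12 UMIs, and no difference was detectable at this depth. Glb1 (ENSMUSG00000045594), which encodes the lysosomal β-galactosidase, was at 35.7 CPM (95% interval 34.3 to 37.1) against 21.6 CPM (18.2 to 25.4). Higher in positive cells were Gdf15 at 308 against 90.4 and Igf1 at 222 against 56.8 CPM, as were Tnf at 258 against 189 and Trem2 at 487 against 353 CPM, both of which were lower without proliferating cells. Lower were Lmnb1 at 57.1 against 155 and Trp53 at 47.5 against 74.9 CPM. Further values were Spp1 at 1343 against 1159.8, Mki67 at 149 against 195 and Il6 at 5.53 against 2.81 CPM, and both Spp1 and Mki67 changed sign in several alternatives. The senescence-associated secreted factors list had a median of 0.23, and of its 63 measured members, 20 were at least 1.5-fold higher and 7 at least 1.5-fold lower. That median was smaller at Leiden resolution 2.0 and with the cluster mix held equal, 0.058 in both, with all 6 libraries clustered together, 0.075, and without proliferating and low-UMI clusters, 0.079. The list of cell cycle inhibitors and p53 targets had a median of -0.39, and of its 13 measured members, 2 were at least 1.5-fold higher and 5 at least 1.5-fold lower, with Cdkn1b at 14.0 against 41.6, Pmaip1 at 19.9 against 46.2 and Plk2 at 258 against 140.3 CPM. Limited to members of at least 50 CPM, its median was 0.13. As a description of these libraries, among 10000 random lists matched on expression the lysosome and secreted factor medians lay at percentile 100, and the inhibitor and p53 median at percentile 0.825.

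**Figure D2:**
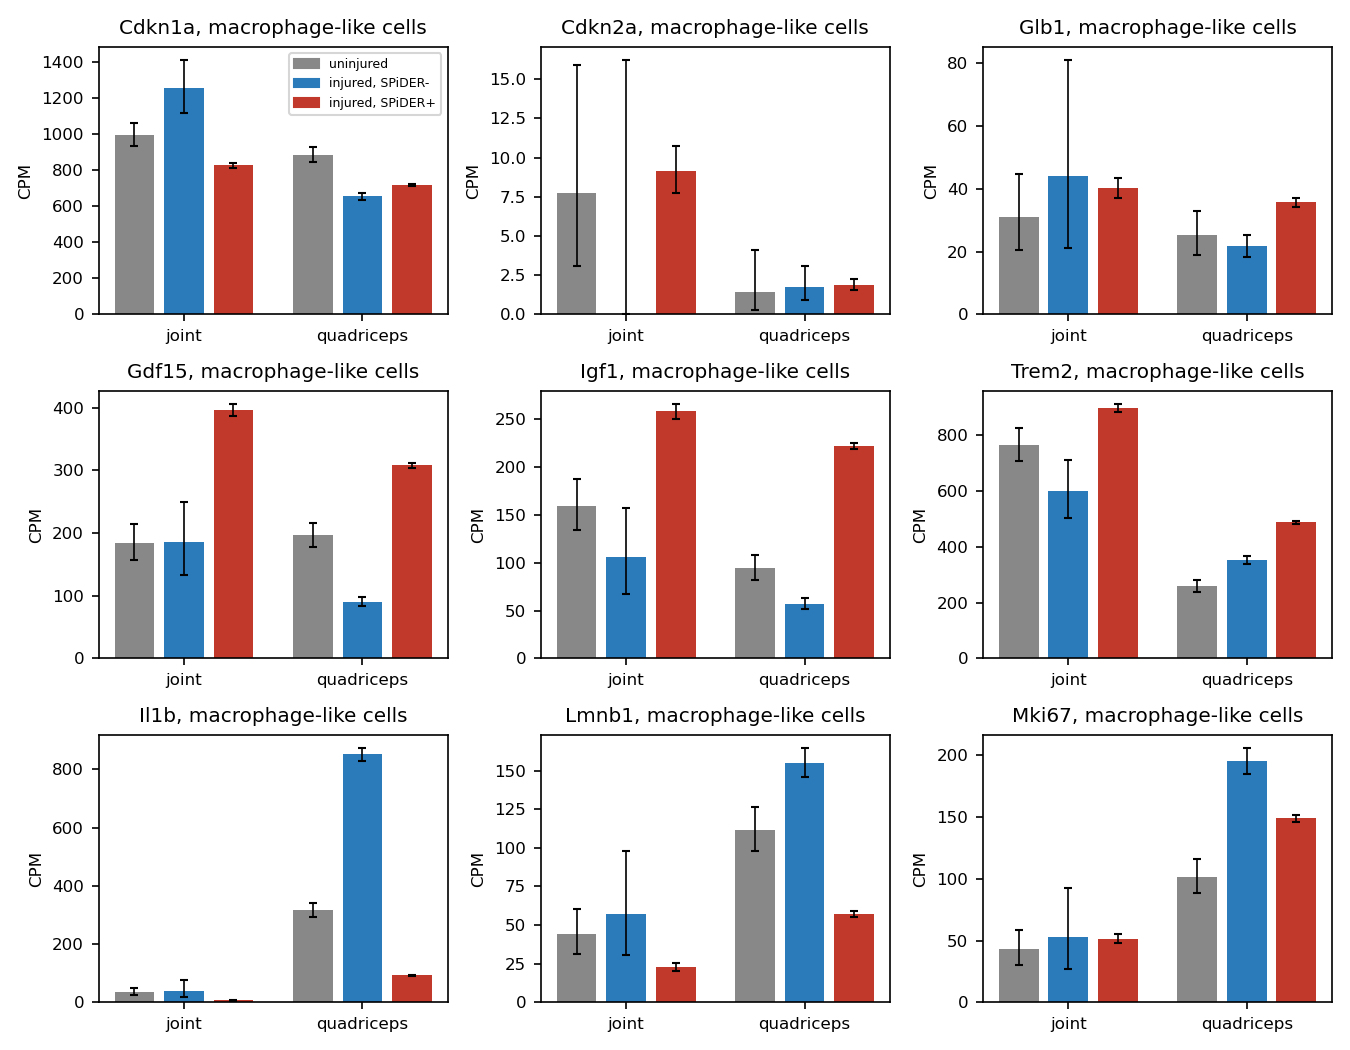
CPM of 9 genes (y axes) in macrophage-like cells of the 6 libraries, with exact Poisson 95% intervals as error bars. In both tissues Gdf15 and Igf1 were higher in SPiDER-positive than in SPiDER-negative cells, with Gdf15 at 308 against 90.4 and Igf1 at 222 against 56.8 CPM in quadriceps.

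The joint sort contrast rested on 36 SPiDER-negative macrophage-like cells with 227036 UMIs. Here too, positive cells had higher resident-type and lysosomal transcripts and lower monocyte transcripts. Cd209f was at 78.9 CPM in the positive cells and had 0 UMIs in the negative cells, at least 5.97-fold higher against a floor of 3 counts. The other genes with the largest positive ratios, in CPM, were Fabp5 at 148 against 17.6, Tfrc at 70.0 against 8.81, C4b at 141 against 22.0, Akr1b8 at 66.0 against 8.81 and S100b at 78.0 against 13.2 CPM. After these came Gclc at 97.4 against 17.6, Clcn4 at 98.9 against 22.0, Npl at 95.5 against 22.0 and Ctla2b at 171 against 44.0 CPM, all but Ctla2b with 5 or fewer UMIs in the negative cells. From 2, 2 and 3 negative UMIs, the folds were 7.95 (2.19 to 65.7) for Tfrc, 7.49 (2.07 to 61.9) for Akr1b8 and 5.91 (2.02 to 28.7) for S100b, with counting intervals in parentheses. Those with the largest negative ratios were Cd74 at 519.9 against 1691, Fos at 591 against 1515, Lyz1 at 208 against 489, Jun at 399 against 916 and Klf2 at 247 against 462 CPM. Next were Malat1 at 26399 against 47037, Ifitm3 at 433 against 758, Egr1 at 318 against 551, Nfkbia at 1054 against 1801 and Glud1 at 304 against 519.7 CPM. With monocyte-like cells counted in, Fabp5, Fos, Lyz1, Jun, Klf2, Malat1, Egr1, Nfkbia and Cdkn1a took the opposite sign, and so did the medians of the MHC class II list, at 0.13, the NF-kB list, at 1.74, the immediate early and heat shock list, at 1.21, and the oxidative phosphorylation list, at -0.093. Of the resident-type list's 19 measured members, 12 were at least 1.5-fold higher and 0 at least 1.5-fold lower, and its median was 0.76, with a range of 0.73 to 5.12 over the alternatives. The lysosome median was 0.37, at percentile 99.98 of the random lists, and of its 34 measured members, 10 were at least 1.5-fold higher and 0 at least 1.5-fold lower, with Ctsd at 3591 against 1321 and Atp6v1b2 at 189 against 74.9 CPM. The recruited monocyte median was -1.78, with Ccr2 at 20.3 against 229 and Plac8 at 5.33 against 189 CPM, Plac8 being at least 2-fold lower in the 3 other joint classes compared too, and the MHC class II median -1.21. The negative cell with the most UMIs of each gene held 66.9% of the Cd74, 44.1% of the Lyz1 and 43.2% of the Egr1 UMIs, and without it these genes were at 577, 291 and 322 CPM in the negative cells. Other medians were 0.66 for collagen and matrix, 0.54 for lipid-associated macrophage and 0.54 for muscle atrophy and denervation. Lower ones were 0.50 for interferon response, 0.46 for iron handling and oxidative stress and 0.30 for oxidative phosphorylation. The next ones were 0.25 for proliferation, 0.13 for complement, 0.11 for matrix proteases and inhibitors and -0.087 for glycolysis and hypoxia. The lowest were -0.26 for secreted factors acting on muscle, -0.38 for immediate early and heat shock and -0.43 for NF-kB and inflammatory cytokines. Ranges over the alternatives were -2.18 to 0.59 for proliferation, 0.072 to 4.65 for complement, -0.88 to 2.25 for matrix proteases, -0.28 to 0.92 for secreted factors acting on muscle, -1.15 to 0.79 for interferon response and -4.01 to -1.28 for recruited monocyte.

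Cdkn1a was lower in the positive joint cells, at 827 CPM (95% interval 813 to 841) against 1255 CPM (1114 to 1409.8). Cdkn2a had 149 UMIs in the positive cells, 9.13 CPM, and 0 UMIs in the negative cells, which allows up to 13.2 CPM, so no difference was detectable. Glb1 was at 40.2 CPM (95% interval 37.2 to 43.4) against 44.0 CPM (21.1 to 81.0), with overlapping intervals. Higher in the positive cells were Gdf15 at 396 against 185, Igf1 at 258 against 106 and Trem2 at 897 against 599 CPM, and lower were Il1b at 7.41 against 39.6 and Lmnb1 at 22.8 against 57.3 CPM. Spp1 was at 309 against 220.2 CPM and took the opposite sign in several alternatives, while Tnf at 307 against 313, Trp53 at 49.5 against 61.7 and Mki67 at 51.4 against 52.9 CPM had overlapping intervals. Il6 had 69 UMIs in the positive and 0 in the negative cells, not a detectable difference at this depth. The senescence-associated secreted factors list had a median of 0.11 at percentile 90.1, with 10 of 60 members at least 1.5-fold higher and 8 lower, and the inhibitor and p53 list one of -0.20 at percentile 10.7. Over the alternatives these ran from -0.0071 to 0.90 and -0.26 to 0.092.

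**Figure D3:**
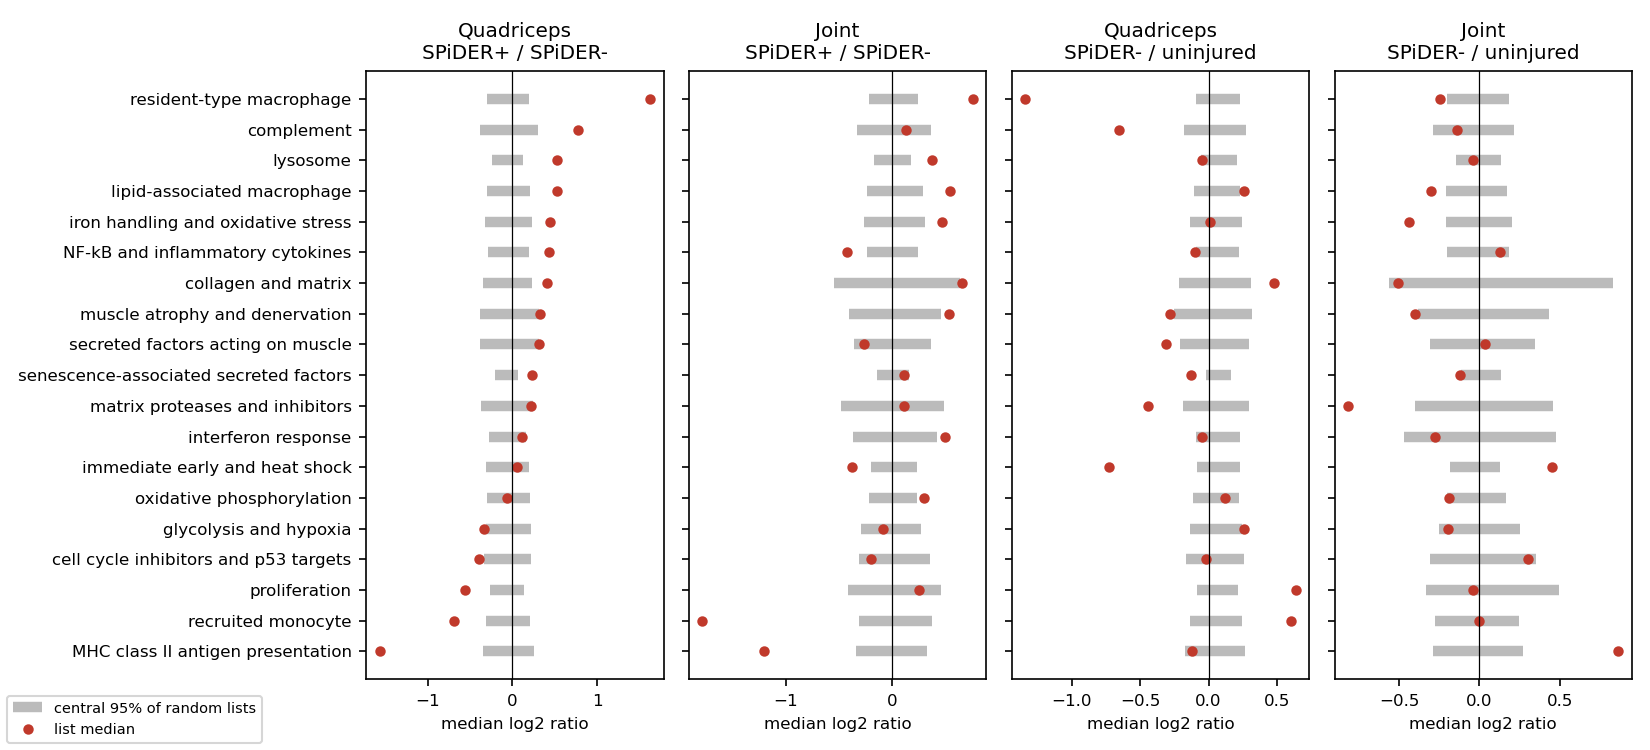
Median log2 ratio (x axes) of each gene list in macrophage-like cells for the 4 comparisons, as points, with the central 95% of medians of 10000 expression-matched random lists as grey bars. The resident-type median was 1.63 in the quadriceps sort contrast, 0.76 in the joint sort contrast and -1.34 in injured SPiDER-negative against uninjured quadriceps. Over the alternatives these ran from 0.53 to 2.22, 0.73 to 5.12 and -1.40 to -0.20.

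The sort contrast was then compared between tissues. Across 2581 genes with at least 50 CPM in either library of both tissues, the log2 ratios had a Pearson correlation of 0.482 and a Spearman correlation of 0.489. These are correlations across genes, which are not independent replicates. At least 2-fold higher in positive cells were 81 genes in quadriceps and 57 in joint, and 19 in both, where 1.79 would be shared if the tissues were independent. The shared genes, with intervals apart in both tissues, were Npl, Mafk, Cd163, Ctsd, Cd209f, Gdf15, Hmox1, Igf1, Ccl8, Wfdc17, Cbr2, Ifi27l2a, Ctla2b, Ftl1-ps1, Stab1, Syngr1, C4b, mt-Nd3 and mt-Nd4l. At least 2-fold lower were 34 and 54 genes, with 14 in both against 0.711 if independent. These, also with intervals apart, were Cytip, Dusp2, Mthfd2, Napsa, Tspan13, Il7r, Csf2rb, H2-DMa, H2-DMb1, H2-Ab1, H2-Aa, H2-Eb1, Lmnb1 and Cd74. Of the shared lower genes 6 belong to MHC class II presentation. Without the 2% of cells, at least 1, with the most UMIs of each gene in its higher library, 17 of the 19 and 13 of the 14 genes were still 2-fold apart in quadriceps, and 12 and 6 in joint. For each of 4 genes 1 negative joint cell held most UMIs, 66.9% of the Cd74, 65.0% of the H2-Ab1, 63.9% of the H2-Aa and 84.1% of the H2-Eb1 ones, and without it they were at 577, 127, 136 and 49.9 against 519.9, 125, 179.6 and 93.2 CPM, so the shared MHC class II difference rested in joint largely on single cells. Ccl8 and Wfdc17 were at least 2-fold higher in each quadriceps class compared, and mt-Nd3 and mt-Nd4l in each joint class compared, so these 4 differed in other classes as well.

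**Figure D4:**
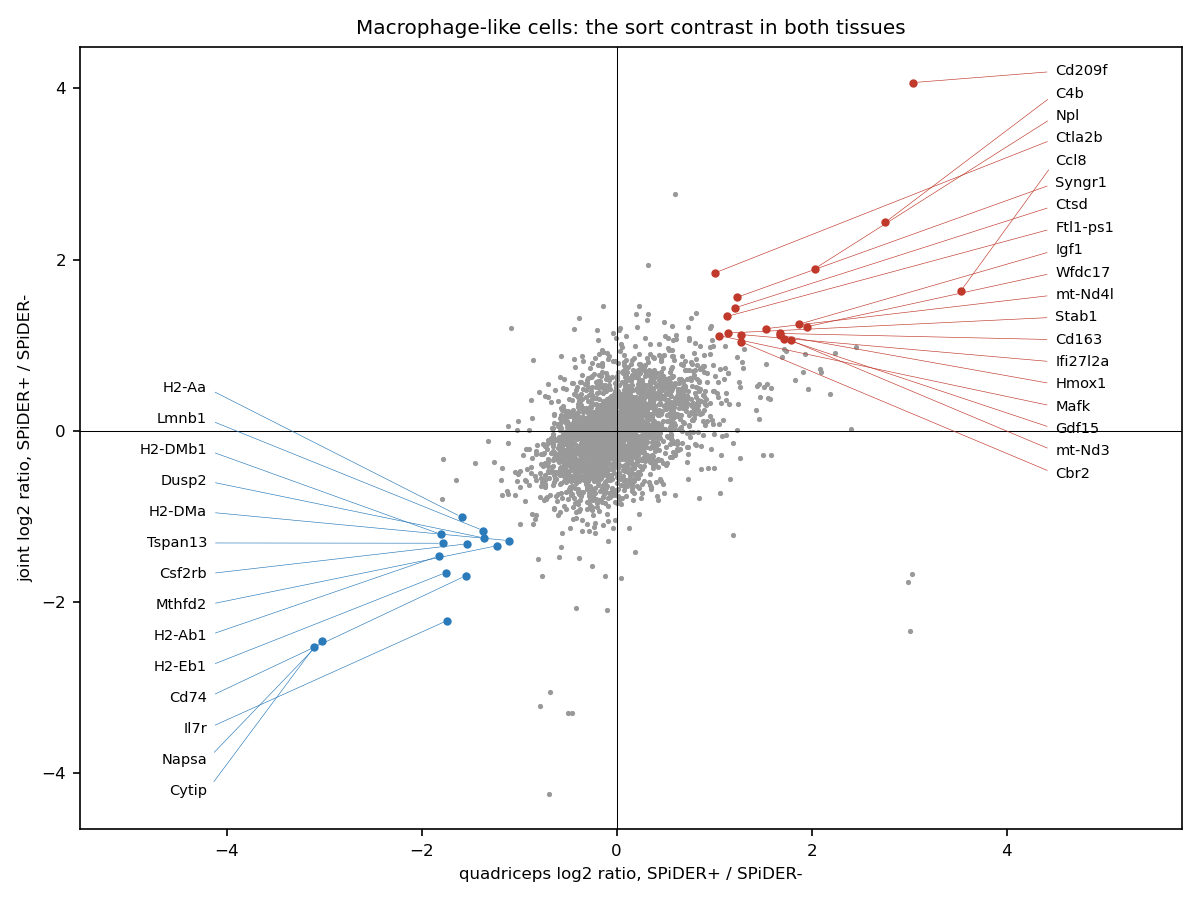
Log2 ratio of SPiDER-positive to SPiDER-negative macrophage-like cells in quadriceps (x axis) and joint (y axis), 1 point per gene, with the 19 genes at least 2-fold higher in both tissues in red and the 14 at least 2-fold lower in blue.

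The quadriceps injury contrast compared SPiDER-negative macrophage-like cells of the injured limb with those of the uninjured limb. Proliferation and monocyte transcripts were higher in these negative cells, and resident-type, complement and immediate early ones lower. The genes with the largest positive ratios, in CPM, were Mmp12 at 102 against 16.9, Ccl17 at 54.3 against 11.7, AA467197 at 76.6 against 21.1, Il1b at 852 against 316 and Cxcl3 at 192 against 74.0 CPM. Smaller ratios were those of Malt1 at 198 against 76.4, Dut at 83.7 against 32.3, Plac8 at 127 against 51.1, Ms4a4c at 156 against 65.6 and Hist1h1b at 749.6 against 343 CPM. Those with the largest negative ratios were Mcpt4 at 0.740 against 85.8, Cma1 at 0.296 against 55.8, Cd209f at 17.3 against 154, Cd209d at 11.5 against 97.9 and Cd209g at 4.88 against 55.8 CPM. Then came Timd4 at 11.1 against 84.4, Colec12 at 7.55 against 54.8, Acp5 at 73.4 against 336, Lyve1 at 87.4 against 381 and Ccl24 at 94.99 against 386 CPM. Mcpt4 and Cma1 are mast cell genes and came from 6 of the 312 uninjured cells each, Cma1 with 2 UMIs in the negative cells and a fold of 0.00531 (0.000635 to 0.0196). The 6 uninjured cells with the most Acp5 UMIs held 96.4% of them, and without these Acp5 was at 13.2 CPM in uninjured cells, below the injured value. Cd209f and Cd209g, also without the 6 highest cells of each, were at 78.8 and 32.5 CPM. Without the 12 negative cells with the most UMIs of each gene, Mmp12 was at 27.6, Ccl17 at 8.27, AA467197 at 44.8, Il1b at 409, Cxcl3 at 76.5 and Plac8 at 66.6 CPM in the injured cells, so that Ccl17 was below its uninjured value. Mmp12, Hist1h1b, Acp5, Mcpt4, Cma1, Igf1 and Lmnb1 each changed sign in at least 1 alternative. Of the resident-type list's 18 measured members, 0 were at least 1.5-fold higher and 12 at least 1.5-fold lower, and its median was -1.34, with a range of -1.40 to -0.20 over the alternatives. Of the proliferation list's 22 measured members, 12 were at least 1.5-fold higher and 0 at least 1.5-fold lower, with Pclaf at 319 against 151, Cdk1 at 53.4 against 25.3 and Mki67 at 195 against 102 CPM. Of the immediate early and heat shock list's 18 measured members, 0 were at least 1.5-fold higher and 12 at least 1.5-fold lower, with Hspa1a at 74.9 against 275, Egr1 at 189 against 458 and Jun at 522 against 1228 CPM. The highest medians were 0.64 for proliferation, 0.60 for recruited monocyte, 0.48 for collagen and matrix and 0.26 for lipid-associated macrophage. The collagen and matrix median ran from -0.85 to -0.022 in 4 alternatives, and the lipid-associated one was -0.048 at Leiden resolution 2.0, -0.022 with all 6 libraries clustered together and -0.019 with unnamed clusters of macrophage markers added. The ranges were 0.044 to 0.78 for proliferation, 0.19 to 1.09 for recruited monocyte, -0.93 to -0.22 for complement and -0.80 to -0.35 for the immediate early list. Medians of the NF-kB, matrix protease, senescence-associated secreted factor, MHC class II, interferon, lysosome, p53, iron handling and oxidative phosphorylation lists also changed sign in at least 1 alternative, that of MHC class II up to 0.22 and that of interferon up to 0.36. Then came 0.26 for glycolysis and hypoxia, 0.12 for oxidative phosphorylation and 0.014 for iron handling and oxidative stress. Those just under 0 were -0.016 for cell cycle inhibitors and p53 targets, -0.047 for lysosome and -0.046 for interferon response. Others were -0.098 for NF-kB and inflammatory cytokines, -0.12 for MHC class II antigen presentation and -0.13 for senescence-associated secreted factors. Lower medians were -0.28 for muscle atrophy and denervation, -0.31 for secreted factors acting on muscle and -0.44 for matrix proteases and inhibitors. The lowest were -0.66 for complement and -0.73 for immediate early and heat shock. Cdkn1a was at 653 CPM (95% interval 634 to 673) against 884 CPM (844 to 925) in injured against uninjured cells, and other lower genes were Gdf15 at 90.4 against 196, Igf1 at 56.8 against 94.2 and Tnf at 189 against 288 CPM, while higher were Spp1 at 1159.8 against 649.5, Trem2 at 353 against 259.6 and Lmnb1 at 155 against 112 CPM. Glb1 at 21.6 against 25.3, Trp53 at 74.9 against 61.4 and Cdkn2a at 1.78 against 1.41 CPM had overlapping intervals. Cluster 3 held 13.002% of the negative and 48.1% of the uninjured cells and cluster 16 27.4% and 11.9%. Median mitochondrial shares were 3.43% and 4.99%. The contrast left out the 5924 positive injured cells, which had higher resident-type transcripts. Whether the uninjured cells were sorted is not known, so a difference of gate was not separable from injury.

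The joint injury contrast set the 36 negative macrophage-like cells against 95 uninjured ones. At least 1.5-fold higher and lower were 3 and 0 of 9 MHC class II, 5 and 0 of 18 immediate early, 0 and 6 of 14 iron handling and 0 and 1 of 9 protease list members. The genes with the largest ratios included Atp6v0c at 1652 against 7.73, Nme2 at 916 against 119 and Ptp4a1 at 4.40 against 157 CPM. Over all cells these genes also lay at least 4-fold outside the range of the other 5 libraries, with Atp6v0c at 5.23, Nme2 at 53.1 and Ptp4a1 at 165 CPM in the uninjured joint library, which has a feature table of its own. Ptp4a1 had 1 UMI in the negative cells, and its fold was 0.0281 with a counting interval of 0.000706 to 0.159. Higher in the negative cells were Lyz1 at 489 against 75.1, Egr1 at 551 against 227, Cd74 at 1691 against 801, Klf9 at 454 against 219 and Fos at 1515 against 741 CPM. Higher genes also included Jun at 916 against 487 and Ifitm3 at 758 against 474 CPM. Lower were Retnla at 30.8 against 196, Cxcl3 at 48.5 against 164, Ccl4 at 115 against 337, Ccl3 at 70.5 against 202 and Entpd1 at 48.5 against 127 CPM. Also lower were Map1lc3a at 48.5 against 120.3, Pea15a at 52.9 against 123, Gsk3b at 61.7 against 137 and Syngr1 at 70.5 against 155 CPM. List medians were 0.87 for MHC class II antigen presentation and 0.45 for immediate early and heat shock. Next were 0.30 for cell cycle inhibitors and p53 targets and 0.13 for NF-kB and inflammatory cytokines. Close to 0 were 0.035 for secreted factors acting on muscle, -0.0028 for recruited monocyte, -0.041 for lysosome and -0.039 for proliferation. Below these were -0.12 for senescence-associated secreted factors, -0.14 for complement and -0.19 for oxidative phosphorylation. Still lower were -0.19 for glycolysis and hypoxia, -0.25 for resident-type macrophage and -0.28 for interferon response. Then came -0.30 for lipid-associated macrophage, -0.40 for muscle atrophy and denervation and -0.44 for iron handling and oxidative stress. Lowest were -0.51 for collagen and matrix and -0.82 for matrix proteases and inhibitors. Cdkn1a was higher in the negative cells, at 1255 CPM (95% interval 1114 to 1409.8) against 995 CPM (931 to 1062). In the positive injured cells it was below the uninjured value. The intervals overlapped for Gdf15 at 185 against 184, Igf1 at 106 against 159 and Glb1 at 44.0 against 30.9 CPM, and for Il1b at 39.6 against 36.4, Tnf at 313 against 416, Spp1 at 220.2 against 269, Trem2 at 599 against 764, Lmnb1 at 57.3 against 44.2, Mki67 at 52.9 against 43.1 and Trp53 at 61.7 against 46.4 CPM. Cdkn2a had 0 UMIs in the negative and 7 UMIs, 7.73 CPM, in the uninjured cells, and Il6 had 0 UMIs in both. Cd74 changed sign when cells with a mitochondrial share of 5% or more were left out, to -0.55, and so did the MHC class II median, at -0.44. With monocyte-like cells counted in, the MHC class II median was -0.22 and the immediate early median -0.12. Without the negative cell with the most UMIs of each gene Cd74 was at 577 CPM, below the uninjured value, Lyz1 at 291 and Egr1 at 322 CPM. Without the highest uninjured cell of each gene, Retnla was at 124 and Cxcl3 at 100.3 CPM in uninjured cells. The resident-type median was 0.013 with no doublets removed. The interferon median ran from -0.46 to 1.43, highest with all 6 libraries clustered together, and the NF-kB, proliferation, recruited monocyte, oxidative phosphorylation, secreted factors acting on muscle and p53 medians also took both signs. Retnla, Lyz1, Egr1, Jun, Ifitm3 and Gsk3b changed sign in 1 alternative each.

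Shares of cells with a UMI were counted after each cell was thinned to 2000 UMIs. In quadriceps, macrophage-like cells with a Cdkn1a UMI made up 70.5% (3986 of 5655 cells, 95% interval 69.3 to 71.7%) of the positive, 64.4% (345 of 536 cells, 95% interval 60.1 to 68.4%) of the negative and 73.4% (188 of 256 cells, 95% interval 67.6 to 78.7%) of the uninjured cells. In joint, the Cdkn1a shares were 71.7% (1236 of 1725 cells, 95% interval 69.5 to 73.8%) in positive, 77.1% (27 of 35 cells, 95% interval 59.9 to 89.6%) in negative and 73.7% (70 of 95 cells, 95% interval 63.6 to 82.2%) in uninjured cells. Endothelial-like cells of quadriceps had Cdkn1a shares of 81.6%, 74.7% and 71.2% in the uninjured, negative and positive libraries, and fibroblast-like cells 60.9%, 55.7% and 41.4% in quadriceps and 57.0%, 55.0% and 29.1% in joint. Cdkn2a shares were 0.248% (14 of 5655 cells, 95% interval 0.135 to 0.415%), 0.373% (2 of 536 cells, 95% interval 0.0452 to 1.34%) and 0.391% (1 of 256 cells, 95% interval 0.00989 to 2.16%) in the positive, negative and uninjured quadriceps macrophage-like cells, with 0 of 111 positive endothelial-like cells, which allows up to 2.70%. The positive joint cells had a Cdkn2a share of 1.22% (21 of 1725 cells, 95% interval 0.755 to 1.85%), beside 2.01% in fibroblast-like cells, and 0 of 35 negative and 0 of 95 uninjured cells had one, which allows up to 8.57% and 3.16%. The order of uninjured and positive joint cells turned when thinned to 1000 UMIs, 1.05% against 0.741%, and unthinned, 4.21% against 2.60%. Glb1 shares were 7.21% (408 of 5655 cells, 95% interval 6.55 to 7.92%), 4.85% (26 of 536 cells, 95% interval 3.19 to 7.03%) and 3.12% (8 of 256 cells, 95% interval 1.36 to 6.06%) in positive, negative and uninjured quadriceps cells and 6.90% (119 of 1725 cells, 95% interval 5.75 to 8.20%), 8.57% (3 of 35 cells, 95% interval 1.80 to 23.1%) and 8.42% (8 of 95 cells, 95% interval 3.71 to 15.9%) in joint. The Glb1 shares of fibroblast-like cells were 4.18%, 4.85% and 6.20% in uninjured, negative and positive quadriceps and 3.36%, 3.50% and 4.02% in joint, and those of quadriceps endothelial-like cells 1.01%, 1.78% and 1.80%. Median depths in the same order were 5492, 9879 and 9751 UMIs for macrophage-like, 8176, 8649 and 18564 for fibroblast-like and 3153, 3075 and 4689 for endothelial-like cells of quadriceps, and 9233, 6431 and 9062 and 12852, 10012 and 16844 for macrophage-like and fibroblast-like cells of joint. Macrophage-like cells too shallow to be thinned numbered 56, 87 and 269 in quadriceps and 0, 1 and 46 in joint.

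Cdkn2a was also present outside the macrophage-like cells. In quadriceps satellite or myogenic-like cells it was at 10.2, 75.6 and 131 CPM in the uninjured, negative and positive libraries, from 36, 174 and 286 UMIs. Most of these UMIs lay in the Myog and Chrna1 cluster 24, with 14, 33 and 29 cells, 2.38%, 14.2% and 26.6% of the class. Its median UMI count was 6.70 times the library's, so doublets were not ruled out. Within cluster 24 Cdkn2a was at 41.4, 125 and 168 CPM, and in the Myod1 and Myf5 cluster 18 at 4.65, 2.16 and 4.02 CPM. In SPiDER-negative against uninjured myogenic cells, higher genes included Myog at 423 against 46.5, Chrna1 at 292 against 90.3, Phlda3 at 86.1 against 22.6, Bax at 233 against 89.4 and Ccng1 at 41.7 against 8.46 CPM. The proliferation list had a median of 1.18, with 17 of 22 members at least 1.5-fold higher. Mki67 was at 118 against 145 CPM within cluster 24, and at 4.32 against 0.664 CPM, from 4 and 2 UMIs, within cluster 18. So these differences were not separable from the larger share of cluster 24. In joint, fibroblast-like cells had Cdkn2a at 1.25, 2.67 and 17.5 CPM and synovial lining fibroblast-like cells at 1.67, 7.50 and 15.1 CPM, the latter from 2, 4 and 300 UMIs. Joint chondrocyte-like cells were at 1.71, 12.6 and 2.25 CPM, from 2, 8 and 2 UMIs, and macrophage-like cells at 7.73 CPM in the uninjured and 9.13 CPM in the positive library. Over all cells Cdkn2a was at 0.435, 0.546 and 11.2 CPM in joint and 0.836, 2.84 and 3.47 CPM in quadriceps. These classes and clusters were singled out after their Cdkn2a values were seen.

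**Figure D5:**
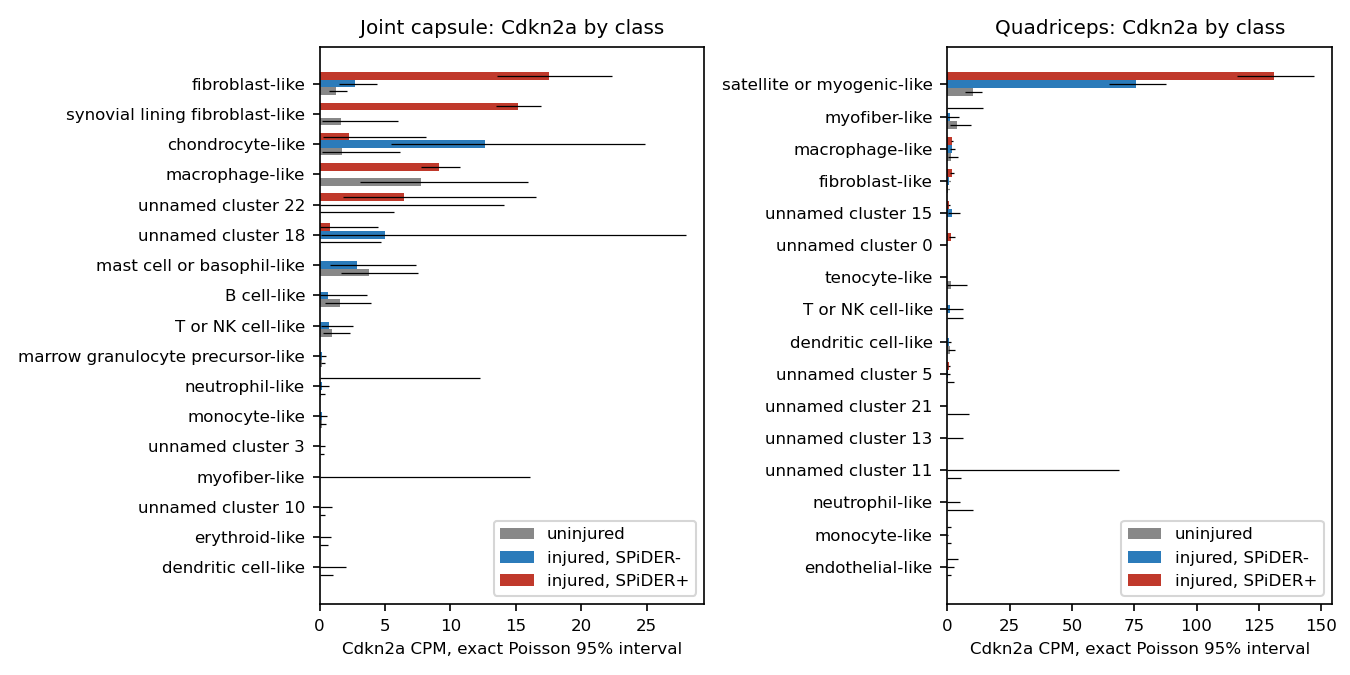
CPM of Cdkn2a (x axes) in each cell class, where the library held at least 50 of its cells, with exact Poisson 95% intervals as error bars. The highest value was 131 CPM, in satellite or myogenic-like cells of the SPiDER-positive quadriceps library, most of it from 29 cells.

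Fibroblast-like cells showed matrix differences in both tissues. In quadriceps, SPiDER-negative against uninjured fibroblast-like cells had higher transcripts of Il1rl1 at 94.9 against 17.6, Cxcl5 at 74.0 against 16.4, Cthrc1 at 292 against 86.1, Postn at 1059.8 against 327 and Plac8 at 161 against 48.5 CPM. Lower were Irgm1 at 49.5 against 113, Ccl11 at 464 against 942, Inmt at 65.7 against 131, Idi1 at 35.6 against 71.4 and F3 at 86.2 against 163 CPM. Of the collagen and matrix list's 21 measured members, 15 were at least 1.5-fold higher and 0 at least 1.5-fold lower, and of the NF-kB and inflammatory cytokines list's 14 measured members, 8 were at least 1.5-fold higher and 0 at least 1.5-fold lower, with Cxcl2 at 1324 against 426 and Timp1 at 403 against 134 CPM. The Postn and Cthrc1 cluster 14 held 3.38% of uninjured, 13.004% of negative and 35.9% of positive fibroblast-like cells. Of negative and positive ones, the Myoc cluster 7 held 16.2% and 5.87%, and the Crispld2 clusters 2 and 6 20.3% and 3.28% and 14.5% and 2.87%. The Pi16 cluster 4 held 10.1%, 27.2% and 50.8% of uninjured, negative and positive ones. So neither the injury differences above nor the sort differences below were separable from this cluster mix. In the quadriceps sort contrast, positive fibroblast-like cells had higher transcripts of Hist1h2ap at 82.8 against 4.46, Serpinb2 at 65.7 against 3.22, Top2a at 70.9 against 6.74, Prc1 at 55.7 against 6.53 and Ube2c at 92.9 against 13.9 CPM. Lower were Myoc at 173 against 908, Inmt at 12.2 against 65.7, Abca8b at 39.2 against 142, Gsn at 4342 against 14204 and Crispld2 at 42.7 against 151 CPM, with Cdkn1a at 335 against 585 CPM. In joint, positive fibroblast-like cells had higher transcripts of Mmp13 at 183 against 9.79, Tnn at 288 against 22.8, C1qtnf3 at 698 against 79.8, Acan at 308 against 34.4, Cthrc1 at 1662 against 219 and Tnc at 333 against 73.7 CPM. Lower were Ccl11 at 10.3 against 213, Ifit1 at 5.13 against 87.4, Abca8b at 9.45 against 83.3, Myoc at 67.7 against 432 and Iigp1 at 5.67 against 58.6 CPM. Msmp was at 129 CPM against 1 UMI, a fold of 726 with a counting interval of 129.7 to 28739. Msmp and Acan are among the 10 leading genes of the chondrocyte-like cluster 21, and chondrocyte-like cells held 2.05% of the positive against 0.613% of the negative library, so chondrocyte RNA or cells within the class were not separable from a fibroblast difference for these genes. Of the collagen and matrix list's 21 measured members, 20 were at least 1.5-fold higher and 0 at least 1.5-fold lower, and of the interferon response list's 16 measured members, 0 were at least 1.5-fold higher and 14 at least 1.5-fold lower. Cdkn1a was lower in these positive cells, at 249 against 629 CPM. Ccl8, Folr2 and Retnla were at least 2-fold higher in each of the 6 quadriceps classes compared. Whether free RNA contributed to this or to the injury differences was not tested in these classes.

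Muscle fibers and cartilage cells gave smaller counts. SPiDER-negative against uninjured myofiber-like cells of quadriceps had higher transcripts of Tnnc1 at 354 against 36.9, Tnni1 at 189 against 29.5, Tpm3 at 372 against 80.3, Tnnt1 at 363 against 79.4 and Myl2 at 144 against 38.8 CPM. Lower genes included Myh2 at 39.8 against 148, Ldhb at 100.03 against 235, Asb2 at 173 against 315 and Mylk2 at 111 against 196 CPM. In the muscle atrophy and denervation list, Sln was higher, at 184 against 65.6 CPM, and the ubiquitin ligase genes Trim63 at 91.6 against 121 and Fbxo32 at 75.4 against 96.9 CPM had overlapping intervals. In joint, SPiDER-positive against negative chondrocyte-like cells (77 against 74) had higher transcripts of Chil1 at 498 against 15.8, Serpina1b at 134 against 14.2, Fxyd3 at 261 against 36.3, R3hdml at 172 against 25.2 and Prkg2 at 169.8 against 29.97 CPM. Lower were Bglap2 at 292 against 3492, Bglap at 457 against 5264, Thbs2 at 18.0 against 170.4, Kctd12 at 21.4 against 189 and Aspn at 159 against 1008 CPM. Of the cartilage matrix list's 14 measured members, 12 were at least 1.5-fold higher and 0 at least 1.5-fold lower, with Col2a1 at 16114 against 5335 and Matn3 at 1375 against 404 CPM, and of the cartilage hypertrophy list's 7 measured members, 0 were at least 1.5-fold higher and 4 at least 1.5-fold lower, with Ibsp at 2897 against 10696, Mmp13 at 237 against 670.4 and Alpl at 289 against 756 CPM. The median log2 ratios of these lists were 1.29 and -1.02. Bglap, Bglap2, Ibsp and Alpl are osteoblast-lineage markers, so osteoblast-lineage cells or RNA among the 74 negative cells were not separable from a chondrocyte difference in either list.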

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

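Of the tests below, those of damaged macrophages and of the gene annotation of the uninjured joint library were chosen after results were seen, and the other 4 before. In macrophage-like cells, 3 gene lists had opposite signs in the 2 tissues. The NF-kB and inflammatory cytokines median of the sort contrast was 0.43 in quadriceps and -0.43 in joint. In injured SPiDER-negative against uninjured cells the lipid-associated macrophage median was 0.26 in quadriceps and -0.30 in joint, and the immediate early and heat shock median -0.73 and 0.45. The opposition was lost in some alternatives. With monocyte-like cells counted in, the joint NF-kB median was 1.74 and the joint immediate early median -0.12. The quadriceps NF-kB median was -0.0020 without proliferating and low-UMI clusters, and without proliferating cells the NF-kB medians were -0.0061 in quadriceps and 0.028 in joint. The quadriceps lipid-associated median was -0.048 at Leiden resolution 2.0, -0.022 with all 6 libraries clustered together and -0.019 with unnamed clusters of macrophage markers added. The causes of these differences between tissues were not tested, nor was the difference itself, and the joint values rest on 36 SPiDER-negative cells.

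Unnamed clusters held part of the cells. Shares of the SPiDER-positive joint library were 4.92% for cluster 18 with osteoclast and macrophage genes such as Acp5, 2.42% for cluster 22 with endothelial and mural genes and 1.20% for the Cxcl12 and Lepr cluster 26. Shares of the SPiDER-positive quadriceps library were 35.9% for cluster 0, 5.41% for the Mmp12 and Retnla cluster 15 and 8.70% for the Gpnmb and Spp1 cluster 5. The low-UMI cluster 13 held 10.1% of the SPiDER-negative quadriceps library. Expression within them was not compared between libraries.

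Macrophage-like cells held 40.2% of the positive against 6.35% of the negative quadriceps library, and 47.1% against 0.298% in joint. For a dye that follows Glb1 expression of each class in the uninjured limb, Spearman's rho of Glb1 with the ratio of shares was 0.152 over 10 quadriceps classes and 0.350 over 12 joint classes, and leaving out 1 class moved the quadriceps value from -0.167 to 0.267, so this and its absence cannot be told apart. A gate that takes cells with more RNA gave a rho of the median UMI count of -0.0424 in quadriceps and 0.0350 in joint, -0.350 to 0.0833 with 1 quadriceps class left out, which also cannot be told apart from no relation. Entry of macrophages that express cell cycle inhibitors was tested on Cdkn1a, whose fold of 1.10 (1.06 to 1.13) in quadriceps lay under the 1.5 set beforehand, which speaks against it for Cdkn1a. The Cdkn2a fold of 1.06 (0.589 to 2.11) from few UMIs leaves Cdkn2a open.

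Cluster 0 of quadriceps, with a median of 901 UMIs per cell, held 35.9% of the positive library. Droplets without a cell that hold free RNA should carry collagen, and the collagen share of its UMIs was 0.596 times (0.583 to 0.609) that of the rest of the library, above the 0.5 set beforehand, so free RNA may account for this cluster. Damaged macrophages were tested on the median mitochondrial share, 1.09 times that of macrophage-like cells, with profile correlations across 7622 genes of 0.959 with macrophage-like cells and 0.951 with the rest, and these cannot be told apart from undamaged ones. Genes are not independent replicates here.

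In joint, 5 genes were at least 2-fold apart in the same direction between the SPiDER-negative and the uninjured library in each of the 10 classes other than macrophage-like cells, namely Ube2v1, Rpl13a, Rnasek, Pabpn1 and Atp6v0c. The same count in the 9 classes of quadriceps was 0. The uninjured joint library has a feature table of its own. Whether its annotation accounts for these genes cannot be told, since a quadriceps count of 0 fixed the outcome of the comparison. Over all cells 20 genes of that library, 5 higher and 15 lower, lay at least 4-fold outside the range of the other 5 libraries.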

How the results depend on the processing

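The alternatives of cluster mix, low-UMI clusters, unnamed macrophage clusters, expected doublet rate, collagen-based free RNA and genes at odds in the uninjured joint library were chosen after results were seen, and the rest before. Of 1917 gene values under alternatives chosen before the data were examined 454 moved, 50 changed sign from a main value with counting intervals apart and 1413 stayed within their limits, and of 614 under added ones 171 moved, 19 changed sign and 424 stayed within their limits. Among 1105 list medians under alternatives chosen before the data were examined 171 moved, 37 changed sign from a main median outside the central 95% of random lists and 897 stayed within their limits, and among 357 under added ones 78 moved, 13 changed sign and 266 stayed within their limits. With sign changes of all other main values counted in, signs differed from the main ones in 98 and 31 gene values and in 127 and 40 list medians, in the same order, and those others are counted above as moved or within their limits. Macrophage-like shares moved in 35 of 42 such cases and 8 of 12 cases added later, and the positive share stayed above the negative one in each. The lysosome median stayed positive in both sort contrasts, from 0.22 to 0.66 in quadriceps and 0.31 to 1.27 in joint. The cause was not tested for any of these moves.

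The median log2 ratio of all genes of the quadriceps sort contrast was -0.0763 and became 0.0464 with trimmed mean factors and -0.119 with the cluster mix held equal. With trimmed mean factors that of the joint injury contrast went from 0.0369 to -0.0703. That of the quadriceps injury contrast was 0.0615 and became 0.109 with free RNA subtracted. Trimmed mean factors, a total without mitochondrial and ribosomal protein genes, matching by symbol, a pseudocount of 1 and collagen-based free RNA changed the sign of 0 genes with counting intervals apart and of 0 lists outside the central 95% of random lists, as did leaving out the genes at odds in the uninjured joint library. Among the other values, trimmed mean factors changed the sign of the oxidative phosphorylation median to 0.068 in the quadriceps sort and of glycolysis to 0.011 in the joint sort contrast. They also changed that of iron handling to -0.0057 in the quadriceps injury and of secreted factors acting on muscle to -0.056 in the joint injury contrast. Mki67 changed to 0.054 and Tnf to 0.072 in the joint sort contrast and Gdf15 to -0.086 in the joint injury contrast. The total without mitochondrial and ribosomal protein genes changed lysosome to 0.00026 in the quadriceps injury and proliferation to 0.023 in the joint injury contrast, and collagen-based free RNA changed Mki67 to 0.043 in the joint sort contrast. Hemoglobin-based free RNA was not run for the quadriceps sort contrast. The cross-tissue correlation was 0.358 at 10 CPM, 0.598 at 200 CPM and 0.475 at a pseudocount of 1.

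At Leiden resolution 0.5, macrophage-like shares moved to 1.63% in joint uninjured, 0.464% in joint negative, 50.4% in joint positive and 5.47% in quadriceps negative. The lysosome median moved to -0.26 in the joint injury contrast. The oxidative phosphorylation median changed sign to -0.11 and Spp1 to -1.22 in the joint sort contrast.

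At Leiden resolution 2.0, macrophage-like shares moved to 1.59% in joint uninjured, 0.448% in joint negative, 50.2% in joint positive, 3.95% in quadriceps uninjured, 13.3% in quadriceps negative and 79.3% in quadriceps positive. The senescence-associated secreted factors median moved to 0.058 and that of lysosome to 0.31 in the quadriceps sort contrast. The proliferation median changed sign to 0.58 and that of MHC class II antigen presentation to 0.014 in the quadriceps sort contrast. The NF-kB and inflammatory cytokines median changed sign to 0.048 and that of lipid-associated macrophage to -0.048 in the quadriceps injury contrast. Cd209a changed sign to 1.65, Hist1h1b to 0.20, Spp1 to -0.48, Mki67 to 0.61, Cdkn1a to -0.013 and Trem2 to -0.039 in the quadriceps sort contrast. Spp1 changed sign to -0.69 in the joint sort contrast.

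With all 6 libraries clustered together, macrophage-like shares moved to 1.73% in joint uninjured, 0.439% in joint negative, 50.4% in joint positive, 5.87% in quadriceps uninjured, 21.7% in quadriceps negative and 90.8% in quadriceps positive. The senescence-associated secreted factors median moved to 0.075 in the quadriceps sort contrast and to -0.032 in the quadriceps injury contrast. The lysosome median moved to -0.23 in the joint injury contrast. The proliferation median changed sign to 0.60 in the quadriceps sort and that of interferon response to -1.15 in the joint sort contrast. The NF-kB and inflammatory cytokines median changed sign to 0.11 and that of lipid-associated macrophage to -0.022 in the quadriceps injury contrast. Cd209a changed sign to 0.29, Hist1h1b to 0.12, Spp1 to -0.15 and Mki67 to 0.68 in the quadriceps sort contrast. Spp1 changed sign to -0.95 in the joint sort contrast. Mmp12 changed sign to -0.053 and Cma1 to 0.034 in the quadriceps injury contrast. Retnla changed sign to 1.00 in the joint injury contrast.

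With at least 800 genes per cell, macrophage-like shares moved to 1.78% in joint uninjured, 0.713% in joint negative, 52.1% in joint positive, 3.53% in quadriceps uninjured and 59.9% in quadriceps positive. The senescence-associated secreted factors median moved to 0.26 and that of lysosome to 0.58 in the joint sort contrast. The lysosome median moved to -0.29 in the joint injury contrast. The oxidative phosphorylation median changed sign to -0.063 and Spp1 to -1.06 in the joint sort contrast. Mcpt4 changed sign to 0.13 in the quadriceps injury contrast.

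With the mitochondrial share under 5%, macrophage-like shares moved to 43.4% in joint positive, 1.74% in quadriceps uninjured and 4.68% in quadriceps negative. In the quadriceps injury contrast the cell cycle inhibitors and p53 targets median moved to -0.26 and that of NF-kB and inflammatory cytokines changed sign to 0.15. The MHC class II antigen presentation median changed sign to -0.44 and Cd74 to -0.55 in the joint injury contrast. Cdkn1a changed sign to -0.0040 in the quadriceps sort contrast.

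With no doublets removed, macrophage-like shares moved to 1.57% in joint uninjured, 0.414% in joint negative, 49.8% in joint positive, 5.14% in quadriceps uninjured, 17.4% in quadriceps negative and 42.4% in quadriceps positive. The lysosome median moved to -0.20 in the joint injury contrast. The proliferation median changed sign to 0.46 in the quadriceps sort contrast. The NF-kB and inflammatory cytokines median changed sign to 0.15, that of matrix proteases and inhibitors to 0.027 and that of senescence-associated secreted factors to 0.0033 in the quadriceps injury contrast. The resident-type macrophage median changed sign to 0.013 in the joint injury contrast. Mki67 changed sign to 0.55 and Spp1 to -0.75 in the quadriceps sort contrast. In the joint sort contrast, Spp1 changed sign to -0.75.

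For macrophage-like and monocyte-like cells together, macrophage-like shares moved to 15.8% in joint uninjured, 11.4% in joint negative, 5.28% in quadriceps uninjured, 18.1% in quadriceps negative and 41.6% in quadriceps positive. In the joint sort contrast, the senescence-associated secreted factors median moved to 0.90 and that of lysosome to 1.27. The proliferation median changed sign to 0.49 and that of collagen and matrix to -0.051 in the quadriceps sort contrast. The MHC class II antigen presentation median changed sign to 0.13, that of immediate early and heat shock to 1.21, that of oxidative phosphorylation to -0.093 and that of NF-kB and inflammatory cytokines to 1.74 in the joint sort contrast. The collagen and matrix median changed sign to -0.57 and that of NF-kB and inflammatory cytokines to 0.088 in the quadriceps injury contrast. The MHC class II antigen presentation median changed sign to -0.22 and that of immediate early and heat shock to -0.12 in the joint injury contrast. Mki67 changed sign to 0.60 and Spp1 to -0.83 in the quadriceps sort contrast. Fabp5 changed sign to -1.21, Fos to 0.40, Lyz1 to 3.63, Jun to 0.91, Klf2 to 1.56, Malat1 to 1.38, Egr1 to 3.49, Nfkbia to 0.62 and Cdkn1a to 0.73 in the joint sort contrast. Lyz1 changed sign to -0.37, Egr1 to -0.24, Cd74 to -0.60, Jun to -0.100, Ifitm3 to -0.056 and Gsk3b to 0.17 in the joint injury contrast.

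Without proliferating cells, the lysosome, senescence-associated secreted factor and NF-kB medians changed sign to 0.17, 0.045 and 0.10 in the quadriceps injury contrast. The collagen and matrix median changed sign to -0.20 in the quadriceps sort contrast. There the NF-kB median changed sign to -0.0061, and to 0.028 in the joint sort contrast. Cd209a changed sign to 1.98, Hist1h1b to 0.46, Spp1 to -0.69, Mki67 to 0.34, Cdkn1a to -0.12, Tnf to -0.19 and Trem2 to -0.15 in the quadriceps sort contrast. Hist1h1b changed sign to -0.55 and Acp5 to 0.32 in the quadriceps injury contrast.

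With the mean of CPM per cell, the lysosome median changed sign to 0.10 in the quadriceps injury contrast. The collagen and matrix median changed sign to -0.28 in the quadriceps sort contrast. In the quadriceps injury contrast, the NF-kB and inflammatory cytokines median changed sign to 0.050. In the quadriceps sort contrast, Spp1 changed sign to -0.31.

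For members with at least 50 CPM, the cell cycle inhibitors and p53 targets median moved to -0.37 in the quadriceps injury contrast. It changed sign to 0.13 in the quadriceps sort contrast. The matrix proteases and inhibitors median changed sign to 0.60 in the quadriceps injury contrast.

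With free RNA subtracted, the senescence-associated secreted factors median moved to -0.024 in the quadriceps injury contrast. The matrix proteases and inhibitors median changed sign to 0.24 there.

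With the cluster mix held equal, the senescence-associated secreted factors median moved to 0.058 and that of lysosome to 0.22 in the quadriceps sort contrast. The cell cycle inhibitors and p53 targets median moved to -0.23 and that of senescence-associated secreted factors to -0.0068 in the quadriceps injury contrast, where that of lysosome changed sign to 0.16. The collagen and matrix median changed sign to -0.18 and that of proliferation to 0.16 in the quadriceps sort contrast. In the quadriceps injury contrast, the NF-kB and inflammatory cytokines median changed sign to 0.087. Mki67 changed sign to 0.47, Cdkn1a to -0.12 and Spp1 to -0.045 in the quadriceps sort contrast. Igf1 changed sign to 0.36 and Lmnb1 to -0.071 in the quadriceps injury contrast.

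With doublets removed up to the expected rate, macrophage-like shares moved to 4.35% in quadriceps negative and 32.1% in quadriceps positive. In the quadriceps injury contrast, the senescence-associated secreted factors median moved to -0.37. There, the collagen and matrix median changed sign to -0.85.

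With unnamed clusters of macrophage markers added, macrophage-like shares moved to 2.10% in joint uninjured, 0.796% in joint negative, 52.1% in joint positive, 4.31% in quadriceps uninjured, 12.5% in quadriceps negative and 90.2% in quadriceps positive. In the quadriceps sort contrast, the lysosome median moved to 0.31. In the joint sort contrast, the senescence-associated secreted factors median moved to 0.31. In the joint injury contrast, the senescence-associated secreted factors median moved to -0.26 and that of lysosome to -0.27. The immediate early and heat shock median changed sign to 0.063 and that of oxidative phosphorylation to -0.040 in the joint sort contrast. The lipid-associated macrophage median changed sign to -0.019, that of collagen and matrix to -0.12 and that of NF-kB and inflammatory cytokines to 0.0033 in the quadriceps injury contrast. Mki67 changed sign to 0.048 and Spp1 to -0.053 in the quadriceps sort contrast. Under this choice, Spp1 changed sign to -1.05 in the joint sort contrast. Mmp12 changed sign to -0.27 and Acp5 to 0.62 in the quadriceps injury contrast.

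Without proliferating and low-UMI clusters, the senescence-associated secreted factors median moved to 0.079 and that of lysosome to 0.29 in the quadriceps sort contrast. Here the senescence-associated secreted factors median moved to -0.029 and that of lysosome changed sign to 0.14 in the quadriceps injury contrast. In the quadriceps sort contrast, the proliferation median changed sign to 0.071 and that of NF-kB and inflammatory cytokines to -0.0020. The NF-kB and inflammatory cytokines median changed sign to 0.085 and that of collagen and matrix to -0.022 in the quadriceps injury contrast. Cd209a changed sign to 1.79, Hist1h1b to 0.32, Spp1 to -0.63, Mki67 to 0.25, Cdkn1a to -0.19, Tnf to -0.26 and Trem2 to -0.16 in the quadriceps sort contrast. Mmp12 changed sign to -0.034 and Acp5 to 0.40 in the quadriceps injury contrast.

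Without thinning, the share of macrophage-like cells with a Cdkn1a UMI was 96.8% in joint uninjured, 91.7% in joint negative, 92.6% in joint positive, 78.8% in quadriceps uninjured, 83.1% in quadriceps negative and 92.9% in quadriceps positive. The Cdkn2a share was 4.21% in joint uninjured, 2.60% in joint positive, 1.77% in quadriceps negative and 1.77% in quadriceps positive. The Glb1 share was 24.2% in joint uninjured, 28.2% in joint positive, 15.4% in quadriceps uninjured, 19.4% in quadriceps negative and 31.2% in quadriceps positive.

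Thinned to 1000 UMIs, the share of macrophage-like cells with a Cdkn1a UMI was 56.8% in joint uninjured, 51.6% in joint positive, 51.3% in quadriceps uninjured, 46.1% in quadriceps negative and 49.98% in quadriceps positive. For Cdkn2a it was 0.741% in joint positive. For Glb1 it was 0% in joint negative, which allows up to 8.57%, 3.82% in joint positive, 1.87% in quadriceps negative and 3.90% in quadriceps positive.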

Other observations

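Monocyte-like cells of quadriceps also differed after injury. In SPiDER-negative against uninjured cells, Areg at 67.6 against 8.54 and Arg1 at 167 against 34.5 CPM were among the higher genes. In myogenic cells of the same comparison the list of cell cycle inhibitors and p53 targets had a median of 0.43, and of its 17 measured members, 7 were at least 1.5-fold higher and 2 at least 1.5-fold lower. The Myog cluster 24 held 14.2% against 2.38% of these cells, and Cdkn1a was not higher within clusters, at 530.5 against 542 CPM in cluster 18 and 605 against 760.4 CPM in cluster 24. The list median was not separable from this cluster mix.

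Genes at least 2-fold higher in each of the 3 joint classes of the sort contrast other than macrophage-like cells were Prg4, C1qb, C1qc, C1qa, Pf4, mt-Nd3 and mt-Nd4l, which include genes of lining and macrophage cells. Those at least 2-fold lower were Chil3, Plac8, Igkc, Hbb-bt, Hbb-bs, Camp, Ngp, Ltf, Prtn3, Elane, Hba-a1, Hba-a2, Mpo and Ctsg, genes of marrow and blood cells.

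Free RNA in macrophage-like cells, as the collagen share over that of the whole library, was 1.56%, 2.14% and 0.963% in uninjured, negative and positive joint and 1.14%, 1.47% and 5.36% in quadriceps. Estimated from hemoglobin it was 3.02%, 2.71% and 1.22% in joint and 15.7%, 5.65% and 148% in quadriceps. Macrophages take up red cells, so hemoglobin counts of the positive quadriceps cells need not be free RNA.

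The median mitochondrial share of kept cells was 5.36% in the positive and 2.02% in the negative quadriceps library, and 3.06% and 1.31% in joint. With 1 pooled library per group, no value here separates the sort or the injury from the preparation of a library.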
